A study of Nothobranchius furzeri with 32 samples.

How the data were processed

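Single-cell RNA-seq of fins of the African turquoise killifish (Nothobranchius furzeri), a short-lived teleost whose fins regrow after amputation, was re-analysed from the deposited files. Per the labels' protocols, fins were dissociated with collagenase, the cells were tagged with CellPlex reagents (oligonucleotide tags that let samples share a droplet run; the files of replicate 2 of the second set hold no tag features), and nucleated live cells were sorted by their Draq5 and DAPI staining. Libraries were made with a Chromium droplet kit that captures the ends of transcripts and tags each molecule with a unique molecular identifier (UMI). The labels name 32 samples in 9 groups from 6 runs.

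The deposited matrices hold raw UMI counts per barcode and gene, with no normalization in the values, and the feature tables give Ensembl gene identifiers and symbols. The submitters' processing notes list Cell Ranger 6.0.1 and Seurat 4.3.0 without their roles, and the genome build is not given in the sources used here, so genes are given by identifier and symbol with no coordinates. The files list 25475 genes, of which 9515 (37.4%) have no symbol. A deposited table of cell counts per library was used for cell calling. The features of the multiplexing tags were left out of the gene counts. The files cannot show how reads shared between near-identical gene copies were counted, so values of genes with a close paralogue (FN1 and FN1B, mmp13a and mmp13b) are uncertain to that extent.

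The libraries form 3 sets. The first holds caudal and dorsal fins that were uncut or at 12 hours post amputation (12 hpa), with 4 caudal uncut, 3 caudal 12 hpa, 2 dorsal uncut and 1 dorsal 12 hpa library. The second holds caudal fins at 12 hpa after a proximal or a distal amputation, with 2 libraries each, and replicate 1 and replicate 2 came from different runs, of which the labels name the first alone as multiplexed. The third holds the uncut dorsal fin of fish whose caudal fin was uncut, amputated proximally or amputated distally, with 3 replicates each; the time after amputation is not given for these in the sources used here. In the third set each replicate has a file labelled 30K and one labelled 50K with different barcodes, and the cells of both were pooled, which makes 23 libraries.

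Cells were kept with at least 500 UMIs, at least 200 genes and at most 20% of UMIs in mitochondrially encoded genes. The 2 files that hold all barcodes were first limited by an order-of-magnitude rule, at 10% of the 99th percentile of the top barcodes up to the deposited cell count, which set thresholds of 5656 and 4730 UMIs. The files of the first set hold no cell under 7681 UMIs, so the minimum of 500 removed none there. Doublets were scored in each library against 2 simulated doublets per cell, and the highest-scoring 0.8% per 1000 cells were removed. Of 86989 called barcodes, 1416 were removed for mitochondrial UMIs and 2399 as doublets, and 83101 cells were kept. The kept cells held between 10886042 and 103574090 UMIs per library, and the median cell held between 9005 and 21708 UMIs.

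Each set was clustered on its own with 2000 variable genes, 30 principal components, 20 neighbours and the Leiden method at resolution 1 (igraph 0.11.9, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). Clusters were assigned to cell classes from 23 lists of markers at 20 CPM (UMIs scaled to a common library total), with a prior of 5 CPM. Clusters with mixed marker scores, with leading genes of another class, or with over 25% doublets were kept out of the classes and stayed in the whole sums. Upper epidermis-like cells comprise intermediate and superficial epidermis, and mesenchyme-like cells comprise fibroblast-like and osteoblast-like cells. Raw counts were summed per library over all kept cells and over basal epidermis-like, upper epidermis-like, mesenchyme-like and macrophage-like cells, with at least 30 cells per class sum.

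Groups were compared with edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr) in R 4.3.3, with 1 fit and 1 shared spread per set, two-sided tests, and Benjamini-Hochberg adjustment over the genes tested at a threshold of 0.05. Because the dorsal 12 hpa group is 1 library, it was assumed to vary like the other groups, and no standard deviation is given for it. Shares of cell classes were tested with edgeR on cell counts, adjusted over classes, with an exact two-sided permutation test beside it; the smallest p that test can give is 0.0286 for 3 against 4 libraries, 0.1 for 3 against 3 and 0.333 for 2 against 2. Each of 25 fixed gene lists was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a contrast and class, and again with an estimated correlation. Of 785 list tests, 275 passed at the preset correlation and 7 passed with an estimated correlation, and those 7 are named where they are reported. A listed symbol was matched ignoring case and a trailing paralogue letter. The lists were fixed without reference to these samples. The up to 200 genes with the smallest p among those up, and among those down, at caudal 12 hpa were tested as sets in the libraries of the other sets.

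Genes named from the whole comparison had to pass at 0.05, carry a symbol, reach a mean of 20 CPM in the higher group and show no overlap between the libraries of the groups; chance gives no overlap for 10% of genes with 3 against 3 libraries. Of these, the 8 largest changes up and the 8 largest down were taken in basal and mesenchyme-like cells, and 4 and 4 in the other classes and whole sums. Up to 4 called members with the smallest p were added per fixed list. sqstm1, mmp9 and mmp13 were named in each contrast whatever their p, and where nothing passed, the 3 genes with the smallest p were named as not called. The contrasts, the lists, this rule and the first set of alternatives were chosen before the data were examined. The genes rab3db (caudal mesenchyme-like cells), mmp13a (dorsal basal cells), and ENSNFUG00015010302, apoda.1, FN1B and GADD45BA (dorsal mesenchyme-like cells) were named after their values were seen, because each is among 5 or fewer genes that passed in its comparison.

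The procedure was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed by known folds. For caudal 12 hpa against uncut, 69.7% of 2-fold changes were recovered in whole sums (13655 genes tested), 50.8% in basal cells (6124 genes) and 40.3% in mesenchyme-like cells (6354 genes). For proximal against distal caudal amputation the shares were 71.2% in whole sums (14848 genes) and 1.7% in macrophage-like cells (3250 genes), and for the dorsal fin after proximal caudal amputation 72.7% (13511 genes) and 6.6% (2024 genes). No simulated change was recovered with the wrong sign.

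Alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors in edgeR, no filter on low counts, replicate number as a block, no doublet removal, at least 1000 UMIs per cell, a knee threshold for the files with all barcodes, the double clustering resolution, each tissue's own libraries, the 30K or the 50K files alone, TMM factors over classes, the estimated correlation, sets of 50 genes, and leaving out each replicate in turn. After the data were seen, 3 more were added: the clusters kept out put back into the class of their best score, the top barcodes up to the deposited cell count, and 1 UMI floor for both replicates of the second set. In the second set the replicate number marks the run, deviations of libraries with the same number correlated at 0.36 across genes (which are not independent replicates), and values with the number as a block are printed beside the counts; in the other sets the number marks nothing in the labels. No pair of replicates had counts within sampling noise of each other (chi-square per degree of freedom between 9.05 and 138), so none was treated as a duplicate. Figures were drawn with matplotlib 3.10.9.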

Results

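Single-cell transcriptomes of killifish fins were compared between uncut and regenerating fins, between amputation planes, and between uncut dorsal fins of fish with and without an amputated caudal fin. The series title names positional information and transient cell states activated by regeneration as its subject. The first set of libraries covered caudal fins (4 uncut libraries, 3 at 12 hours post amputation, written 12 hpa) and dorsal fins (2 uncut, 1 at 12 hpa), with 18147 kept cells. The second covered caudal fins at 12 hpa after proximal or distal amputation (2 libraries each, 23395 cells). The third covered the uncut dorsal fin of fish whose caudal fin was uncut, amputated proximally or amputated distally (3 libraries each, 41559 cells). Kept UMIs ranged from 10886042 to 60249506 per library in the first set, from 74141054 to 103574090 in the second and from 36815929 to 85116533 in the third. The labels do not say that replicates are separate animals, so the p-values measure the spread between these samples. Expression is given as CPM, the summed UMIs of a gene scaled to a common library total, with the SD between libraries. The log2 fold changes carry their standard error (SE), and adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

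At 12 hpa the caudal fin was compared with the uncut caudal fin. FN1B (ENSNFUG00015003666), which encodes the matrix protein fibronectin, rose from 6.42 ± 0.952 CPM (n = 4) to 50.2 ± 13.7 CPM (n = 3), a log2 fold change of 2.97 (SE 0.18, edgeR adjusted p = 1.88e-05). mmp13a (ENSNFUG00015016769), a collagenase, rose from 4.20 ± 0.794 to 37.2 ± 25.2 CPM (log2 3.16, SE 0.38), and anxa2b, a calcium-dependent membrane-binding annexin, from 6.59 ± 1.74 to 76.8 ± 35.4 CPM (log2 3.55, SE 0.30). id3, an inhibitor of basic helix-loop-helix transcription factors, fell from 29.1 ± 0.426 to 14.6 ± 3.09 CPM (log2 -1.0), and IRF1B, an interferon regulatory factor, from 25.6 ± 4.33 to 13.0 ± 3.21 CPM (log2 -0.98). BX511257.1 also rose (log2 2.15), RNF175, a RING finger protein, fell (log2 -1.22), and atf3, a stress-induced transcription factor, fell (log2 -0.91, edgeR adjusted p = 0.0251).

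**Figure D1:**
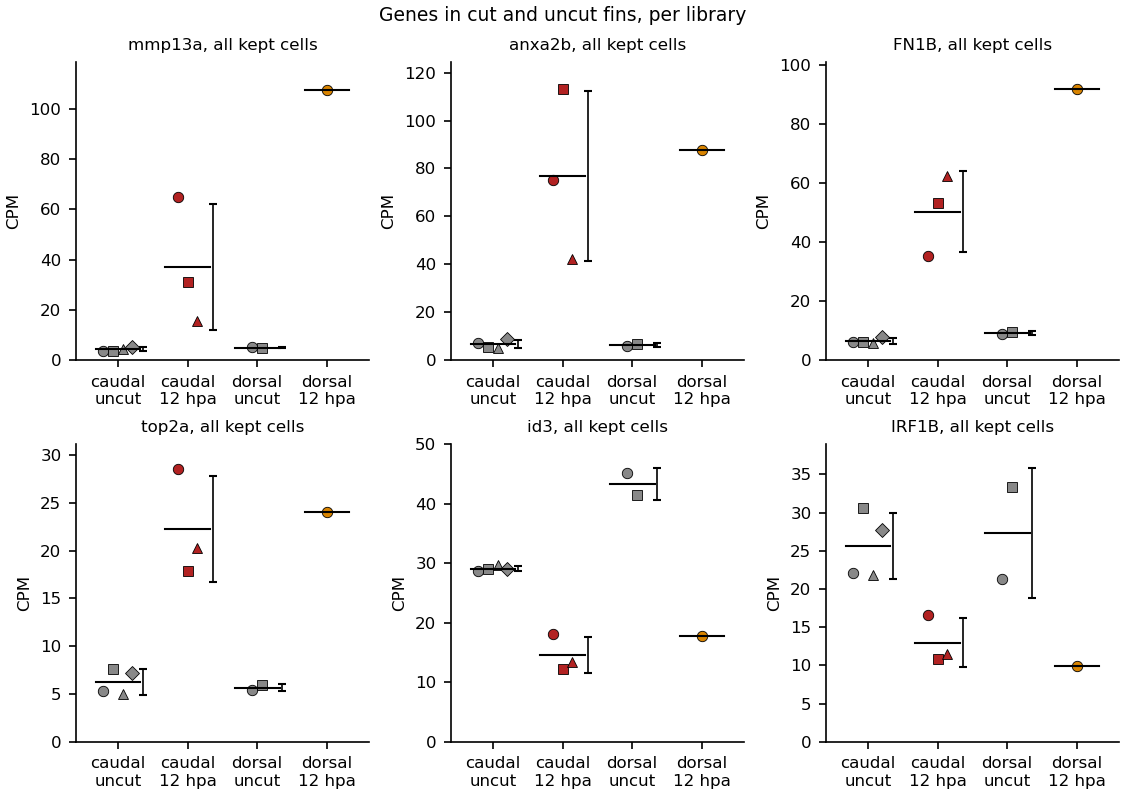
CPM of mmp13a, anxa2b, FN1B, top2a, id3 and IRF1B over all kept cells in uncut and 12 hpa caudal and dorsal fins, with 1 point per library, a line at the mean and a bar for the SD beside it. In the caudal fin FN1B rises from a mean of 6.42 to 50.2 CPM and id3 falls from 29.1 to 14.6 CPM, and the dorsal 12 hpa group is 1 library with no SD.

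Of 14240 genes tested in sums over all kept cells, 1424 rose and 815 fell. The wound protease mmp9 rose as well, from 0.326 ± 0.248 to 1.95 ± 1.86 CPM (log2 2.57, edgeR adjusted p = 0.0245), whereas mmp13b was at 0.0167 CPM in the uncut fin and 0.0509 CPM at 12 hpa (adjusted p = 0.426). sqstm1 (ENSNFUG00015002500), a receptor of selective autophagy, was at 44.4 ± 4.22 CPM at 12 hpa and 44.5 ± 4.71 CPM in the uncut fin (log2 -0.00, adjusted p = 0.992), and its fitted sign turned under 5 of the alternatives. A cluster of cells that was kept out of the cell classes, led by FN1B, anxa2b and mmp13a, held 6.17% ± 0.751 of kept caudal cells at 12 hpa and 0.159% ± 0.180 of uncut cells. All clusters kept out together held 8.07% ± 0.196 and 1.97% ± 0.740.

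Genes of the cell cycle rose together in the caudal fin. Of 21 measured genes of G2 and M phase, 19 rose (20 adjusted over the list alone), with a median log2 fold change of 2.0 (camera adjusted p = 4.4e-36, and 0.0415 with an estimated correlation). Among them were top2a, a topoisomerase that untangles chromosomes (log2 1.83, SE 0.18), and ube2c, a ubiquitin-conjugating enzyme of mitotic exit (log2 2.06, SE 0.21). Of 24 S phase genes, 20 rose (22 adjusted over the list alone), with a median of 0.93 (adjusted p = 0.408 with an estimated correlation), including FEN1, a flap endonuclease of DNA replication (log2 1.07), and the nucleotide enzymes DUT (log2 1.29) and rrm2b (log2 1.21).

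Proteasome and some folding genes rose too. Of 34 proteasome genes, 31 rose (31 adjusted over the list alone). The median was 0.56 (camera adjusted p = 1.8e-38, and 0.0353 with an estimated correlation). The regulatory particle genes psmc4 and PSMD2 rose by log2 1.02 and 0.83. Of 23 genes of the unfolded protein response, 12 rose and 2 fell (14 and 2 adjusted over the list alone). The median was 0.59 (adjusted p = 0.0415 with an estimated correlation). Those called included the endoplasmic reticulum chaperones PDIA3 (108 against 51.7 CPM) and HSP90B1 (57.4 against 29.6 CPM). The 20 heat shock genes gave 6 up and 1 down (7 and 1 adjusted over the list alone). The median was 0.20 (adjusted p = 0.185 with an estimated correlation).

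Of 29 metalloproteinase and protease-regulator genes, 10 rose and 1 fell (12 and 1 adjusted over the list alone). The median was 0.49 (adjusted p = 0.0415 with an estimated correlation). Among those called were mmp13a, mmp9 and the protease inhibitor SERPINE2 (log2 0.83). Of 27 genes of provisional and fibrillar matrix, 9 rose and 1 fell (12 and 1 adjusted over the list alone). The median was 0.91 (camera adjusted p = 6.5e-06, and adjusted p = 0.608 with an estimated correlation). Those called included FN1B and lum, which encodes the collagen-binding lumican (log2 1.02). Of 23 fibroblast markers 9 rose (median log2 0.95). Of 25 immediate early and AP-1 genes 6 fell and 0 rose (8 and 1 adjusted over the list alone). The median was -0.32 (adjusted p = 0.612 with an estimated correlation). Among those called was FOS (log2 -0.57). Of 18 interferon response genes 6 fell (8 adjusted over the list alone). The median was -0.61 (adjusted p = 0.471 with an estimated correlation). Of 55 ribosomal protein genes 39 fell (51 adjusted over the list alone). The median was -0.27 (adjusted p = 0.608 with an estimated correlation).

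Within basal epidermis-like cells, the layer that rests on the basement membrane, mmp13a rose from 10.8 ± 2.94 to 77.7 ± 40.0 CPM (log2 2.83, SE 0.31, edgeR adjusted p = 0.000308). The calcium-binding protein gene S100A2 rose by log2 2.42, the Krüppel-like factor gene KLF2 by log2 2.28, and calr, a calcium-binding chaperone of the endoplasmic reticulum, from 9.61 ± 2.11 to 36.1 ± 9.80 CPM. cenps (log2 1.85), FKBP14 (log2 1.52), DPP3 (log2 1.41) and the chromatin assembly factor gene CHAF1A (log2 1.32) rose as well. XBP1, a transcription factor of the unfolded protein response, fell from 31.9 ± 7.68 to 13.1 ± 2.04 CPM (log2 -1.28), the chromatin protein gene HMGB1A by log2 -1.08 and the immunoglobulin receptor gene pigr by log2 -1.08. In all, 112 genes rose and 61 fell of 6599 tested. Of 23 S phase genes 9 rose (17 adjusted over the list alone). The median was 0.91 (adjusted p = 0.189 with an estimated correlation). Those called included pcna, the replication clamp (484 against 231 CPM), and mcm6, a subunit of the replicative helicase (56.3 against 26.6 CPM).

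In upper epidermis-like cells 1363 genes rose and 649 fell of 12968 tested. CENPF, a kinetochore protein gene, rose from 2.33 ± 0.749 to 20.6 ± 6.59 CPM (log2 3.13, SE 0.24, edgeR adjusted p = 2.98e-05), anxa2b by log2 2.83 and top2a by log2 2.16, and 21 of 22 G2 and M phase genes rose (21 adjusted over the list alone). The median was 2.27 (adjusted p = 0.0724 with an estimated correlation). id3 fell there by log2 -1.13 and IRF1B by log2 -0.89. In mesenchyme-like cells 1 gene passed: rab3db, named after its value was seen, fell from 29.2 ± 5.35 to 4.31 ± 1.47 CPM (log2 -2.69, SE 0.27), while 650 of 7231 genes had an unadjusted p under 0.05 and DESeq2 called 6 up and 12 down. The epidermal keratin krt5 stood at between 13330 and 28300 CPM in the caudal 12 hpa mesenchyme-like sums and between 22300 and 56940 CPM in the uncut ones. The count over all cells was 1182 without 12 hpa replicate 1 and 1467 without uncut replicate 4. The basal count of 173 was 101, 59 and 53 without 12 hpa replicates 1, 2 and 3, 68 without uncut replicate 4, and 453 at the double clustering resolution, and the mesenchyme-like count was 49 without 12 hpa replicate 2, 2 without 12 hpa replicate 3, and 3, 7 and 2 without uncut replicates 1, 2 and 4.

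The dorsal fin at 12 hpa was compared with the uncut dorsal fin on the same fit, and its lone 12 hpa library was assumed to vary like the other groups. S100A2 (ENSNFUG00015020767) was at 144 CPM in that library and 11 ± 0.992 CPM in the 2 uncut libraries (log2 3.70, SE 0.30, edgeR adjusted p = 0.000157). mmp13a was at 108 against 4.90 ± 0.137 CPM (log2 4.46, SE 0.60), anxa2b at 87.9 against 6.29 ± 0.805 CPM (log2 3.83), FN1B at 91.7 against 9.13 ± 0.534 CPM (log2 3.33) and its paralogue FN1 at 21.4 against 1.94 CPM (log2 3.55). OSR1, a zinc finger transcription factor, fell from 213 ± 10.3 to 86.7 CPM (log2 -1.30), id3 by log2 -1.29, IRF1B by log2 -1.44 and the water and glycerol channel gene AQP3 by log2 -1.22 (edgeR adjusted p = 0.0315).

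Over all cells 1117 genes rose and 516 fell of 14240 in the dorsal fin. Of 34 proteasome genes 31 rose (34 adjusted over the list alone). The median was 0.84 (adjusted p = 0.0328 with an estimated correlation). Those called included psmc4 (log2 1.21) and PSMC5 (70.6 against 33.0 CPM). Of 23 unfolded protein response genes 13 rose (14 adjusted over the list alone). The median was 0.97 (adjusted p = 0.0328 with an estimated correlation). Among those called were DNAJB11 at log2 1.14 and PDIA3 at log2 1.02. Of 21 G2 and M phase genes 17 rose (18 adjusted over the list alone). The median was 1.95 (adjusted p = 0.136 with an estimated correlation). Those called included top2a at 24.0 against 5.67 CPM. Of 24 S phase genes 15 rose (24 adjusted over the list alone). The median was 1.33 (adjusted p = 0.358 with an estimated correlation). Of 33 ribosome biogenesis genes 7 rose (7 up and 1 down adjusted over the list alone). The median was 0.36 (adjusted p = 0.507 with an estimated correlation). Among those called was NCL at log2 0.71. mmp9 (log2 2.71, adjusted p = 0.117), mmp13b (log2 3.06, adjusted p = 0.26) and sqstm1 (log2 -0.15, adjusted p = 0.583) did not pass. Of 16 macrophage markers 5 were lower in the dorsal 12 hpa library and 11 did not pass (median log2 -1.06).

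In dorsal upper epidermis-like cells 892 genes rose and 373 fell, with mmp13a (log2 3.58), S100A2 (log2 3.55) and top2a (log2 2.48) up and OSR1 (log2 -1.24) down, and the largest cluster of these cells was cluster 1 at 12 hpa (23.8%) and cluster 6 in the uncut fin (19.1%). In dorsal basal cells mmp13a passed alone, at 175 against 9.76 ± 5.76 CPM (log2 3.97, edgeR adjusted p = 0.00402), and in mesenchyme-like cells 4 genes rose: ENSNFUG00015010302 (log2 3.98), apoda.1 of the apolipoprotein D family (log2 3.71), FN1B (83.8 against 14.3 ± 5.85 CPM) and the growth arrest gene GADD45BA (log2 2.38). These genes were named after their values were seen. The 12 hpa sum held 61 mesenchyme-like cells, and ENSNFUG00015010302 leads a superficial epidermis-like cluster and apoda.1 an iridophore-like one, so these sums can hold transcripts of other cells. The mesenchyme-like cells of the dorsal fin came mostly from an osteoblast-like cluster (80.3% at 12 hpa, 72.0% uncut) and those of the caudal fin mostly from a fibroblast-like cluster (74.3% and 78.5%), and clusters kept out held 15.3% of the dorsal 12 hpa cells and 1.95% ± 0.170 of the uncut ones. Without dorsal uncut replicate 1 the count of 1633 over all cells was 392 and the upper count of 1265 was 228, and without either uncut replicate no basal or mesenchyme-like gene passed, while the dorsal libraries alone gave 42 basal and 47 mesenchyme-like genes.

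Whether the caudal and dorsal responses at 12 hpa differ was tested on the difference itself. No single gene passed in any class, and the direction was shared for most: 791 genes rose and 281 fell in both fins, where independent calls would give 112 and 29.5, and 95% of the genes called in the caudal fin had the same sign in the dorsal fin. The genes with the smallest p over all cells were S100A2 (log2 -2.24, SE 0.35, edgeR adjusted p = 0.255), ACSF2, an acyl-CoA synthetase (log2 1.78, adjusted p = 0.255), and the troponin gene tnnc1b, which lay under 1 CPM. In mesenchyme-like cells they were GADD45BA (log2 -2.29, adjusted p = 0.0717), apoda.1, which leads the iridophore-like cluster (log2 -3.86, adjusted p = 0.0717), and FN1B (log2 -2.09, adjusted p = 0.251), in basal cells GADD45BA, nop2 and FN1B (adjusted p = 1), and in upper cells MFAP4 and limch1b. The difference was -1.29 for mmp13a (adjusted p = 0.662), -0.15 for mmp9 (adjusted p = 0.992), -1.20 for mmp13b (adjusted p = 0.939) and 0.15 for sqstm1 (adjusted p = 0.853).

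edgeR called 0 genes of the difference, with an unadjusted p under 0.05 for 1231 genes over all cells, 243 in basal, 1044 in upper and 501 in mesenchyme-like cells, where DESeq2 called 9, 0, 1 and 1. At the level of gene lists, 7 differed with the preset correlation. Ribosome biogenesis was lower in the caudal than in the dorsal response (median log2 -0.53, camera adjusted p = 9.6e-18, and adjusted p = 0.231 with an estimated correlation), with 0 of 33 genes called and 9 down adjusted over the list alone. The unfolded protein response (median -0.42, adjusted p = 0.231 with an estimated correlation) and the proteasome (median -0.19, adjusted p = 0.342 with an estimated correlation) were lower as well. The interaction rests on 1 dorsal 12 hpa library, and tissue and run go together in it, so the tissue and the run cannot be told apart.

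**Figure D2:**
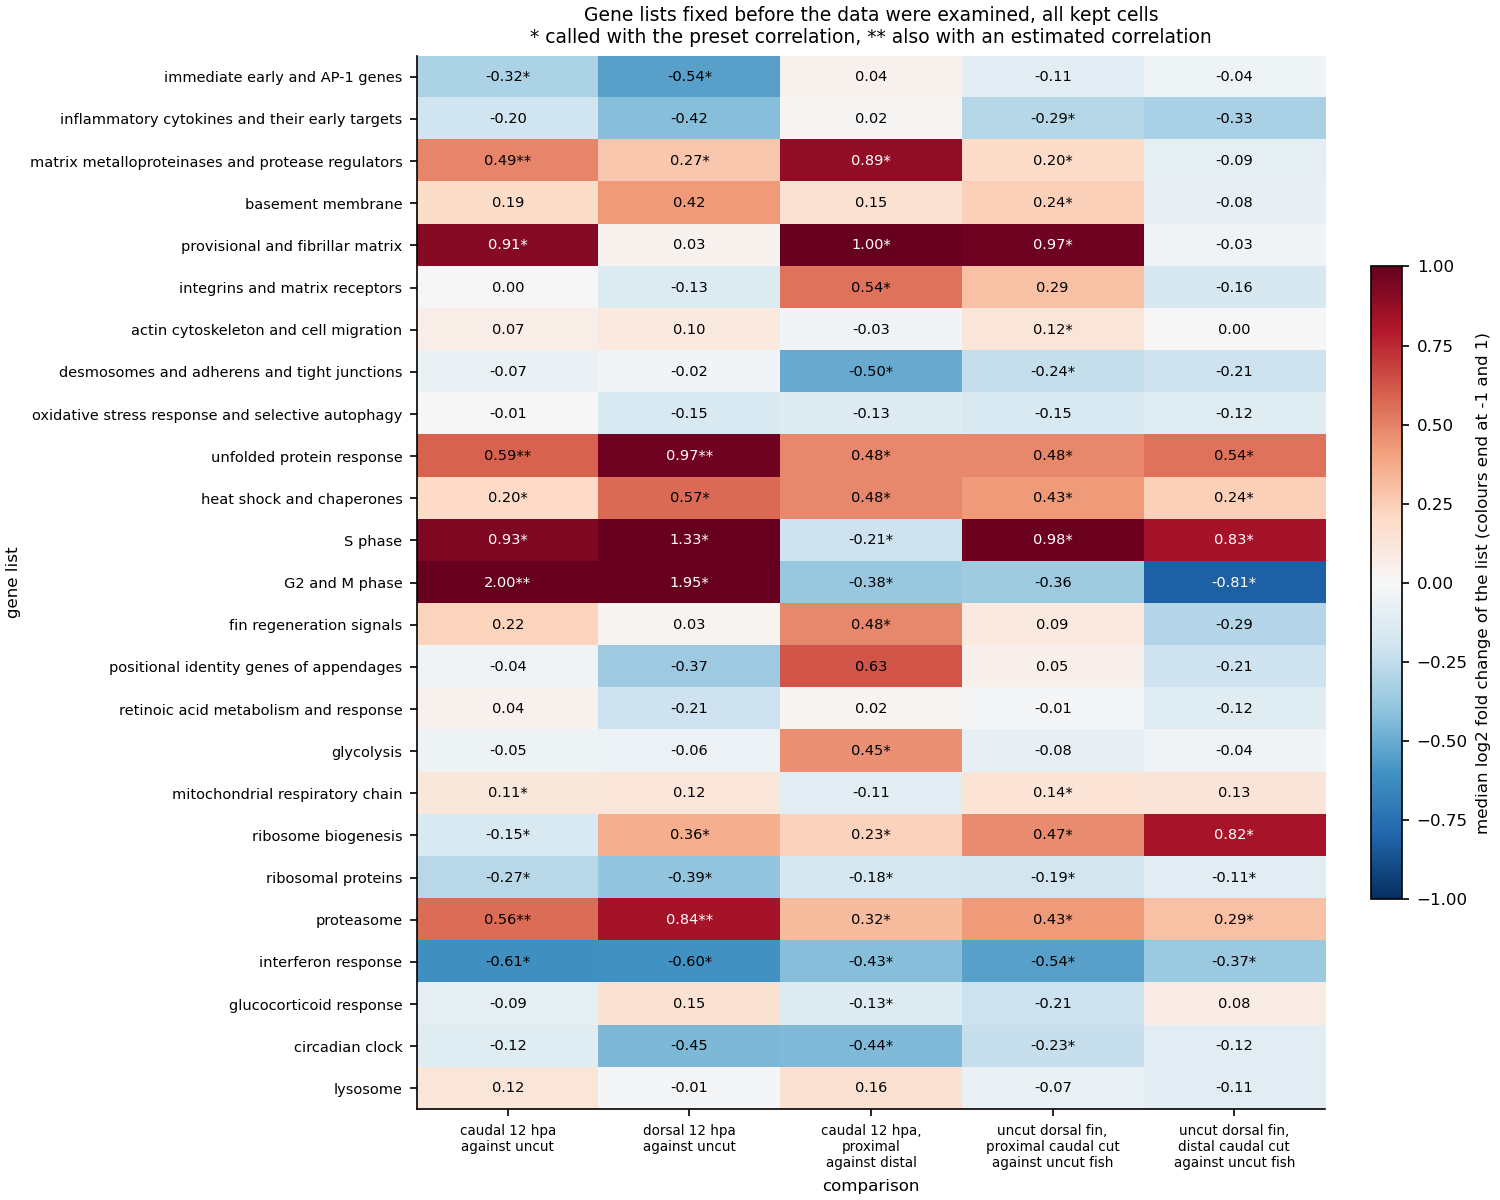
Median log2 fold change of the measured members of 25 fixed gene lists (down the map) in sums over all kept cells, for 5 comparisons (across it), with 1 star where camera passed with the preset correlation and a pair of stars where it also passed with an estimated one. G2 and M phase genes have medians of 2.0 and 1.95 at caudal and dorsal 12 hpa, and the matrix list has a median of 1.00 after proximal against distal caudal amputation.

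Proximal and distal caudal cuts were compared at 12 hpa, with no uncut library of either plane, so prior differences stay open. TNFAIP6, a hyaluronan-binding protein gene, was at 37.7 ± 11 CPM after proximal and 3.92 ± 0.0941 CPM after distal amputation (n = 2 each, log2 3.26, SE 0.21, edgeR adjusted p = 0.000873). FN1B was at 353 ± 36.7 against 96.7 ± 5.84 CPM (log2 1.87, SE 0.11), SPP1, which encodes the bone matrix protein osteopontin, at 31.3 ± 3.17 against 7.32 ± 0.164 CPM (log2 2.10), pyyb, a peptide hormone gene, at log2 3.08 and the pentraxin gene ptx3a at log2 2.97. Distal stumps held more SAA (ENSNFUG00015018792), an acute-phase serum amyloid, at 72.9 ± 15.5 against 9.26 ± 1.41 CPM (log2 -2.98, SE 0.18), and more DAPL1 (262 ± 13.9 against 71.6 ± 4.14 CPM, log2 -1.87), ppdpfa (log2 -2.41) and bpifcl (log2 -1.78). Both libraries of a group came from different runs, and within each run the log2 difference was 2.76 and 3.40 for TNFAIP6, 2.15 and 1.90 for SPP1, -2.54 and -3.27 for SAA and -1.87 and -1.86 for DAPL1.

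**Figure D3:**
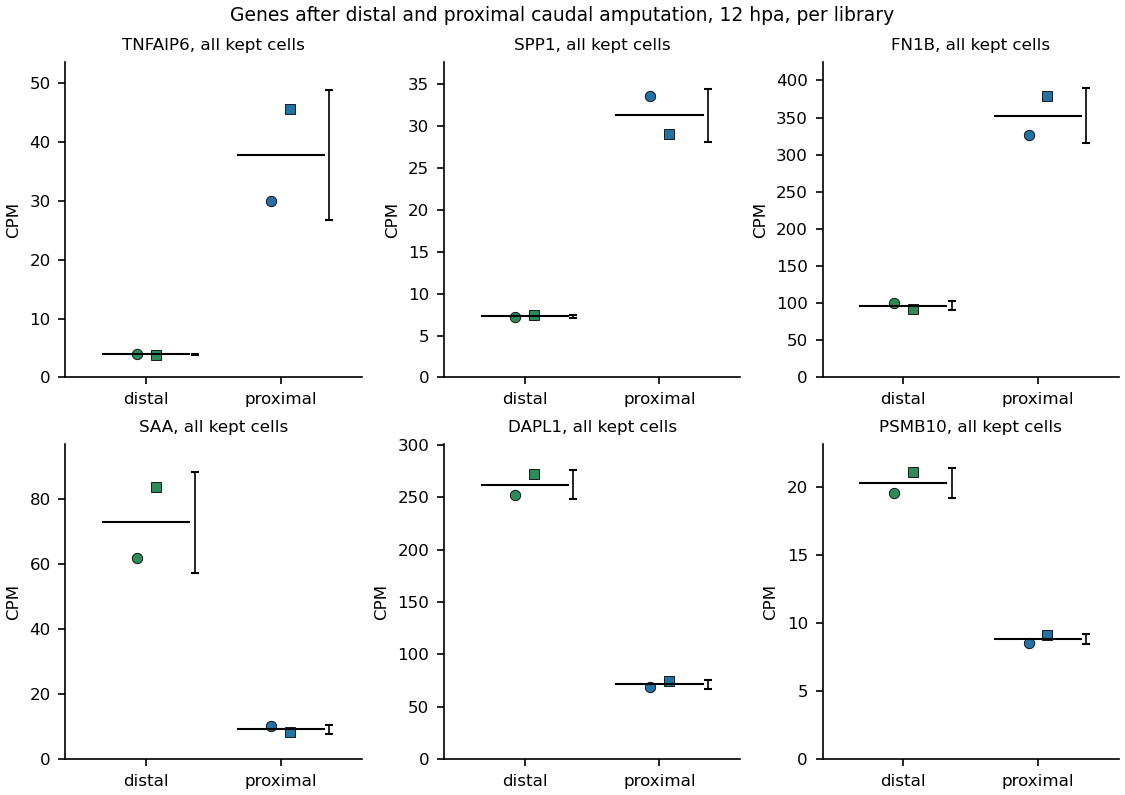
CPM of TNFAIP6, SPP1, FN1B, SAA, DAPL1 and PSMB10 over all kept cells of caudal fins at 12 hpa after distal or proximal amputation, with 1 point per library, a marker shape per replicate number, a line at the mean and a bar for the SD. SAA has means of 72.9 CPM after distal and 9.26 CPM after proximal amputation, and FN1B of 96.7 and 353 CPM.

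Over all cells 2197 genes were higher and 1949 lower after proximal amputation, of 15072 tested, and with the run as a block 3779 and 3798. mmp13a was higher proximally (147 ± 12.2 against 74.1 ± 8.82 CPM, log2 0.99, edgeR adjusted p = 0.00266), as were mmp9 (7.22 ± 0.146 against 2.86 ± 0.522 CPM, log2 1.34) and mmp13b (1.07 ± 0.402 against 0.0398 ± 0.0563 CPM, log2 4.71). sqstm1 was at 102 ± 2.56 against 85.2 ± 6.73 CPM (log2 0.26, adjusted p = 0.0772) over all cells and passed in basal cells (79.4 ± 17.3 against 45.4 ± 2.68 CPM, log2 0.82, edgeR adjusted p = 0.0269).

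Of 32 genes of provisional and fibrillar matrix, 20 were higher proximally and 0 lower (25 adjusted over the list alone). The median was 1.00 (camera adjusted p = 3.4e-15, and adjusted p = 0.352 with an estimated correlation). Those called included FN1 (log2 1.68), the thrombospondin gene THBS1 (log2 1.68) and col6a1 (log2 1.01). Mesenchyme-like cells made up 14.9% ± 2.83 of proximal and 6.31% of distal cells, 18 of 25 fibroblast markers were higher (median log2 1.01), and within mesenchyme-like cells the matrix list had a median of -0.29 (camera adjusted p = 0.454). Of 30 metalloproteinase and protease-regulator genes 17 were higher and 2 lower (17 and 2 adjusted over the list alone). The median was 0.89 (adjusted p = 0.306 with an estimated correlation). Among those called were the collagen-degrading cathepsin CTSK (log2 1.54), MMP14B (log2 1.38) and the inhibitor TIMP2A (log2 1.34). Integrins and matrix receptors gave 11 higher and 2 lower of 24 (12 and 2 adjusted over the list alone). The median was 0.54 (adjusted p = 0.306 with an estimated correlation). Those called included ITGB1 at log2 1.27.

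Of 43 genes of fin regeneration signals 16 were higher proximally and 3 lower (19 and 4 adjusted over the list alone). The median was 0.48 (adjusted p = 0.306 with an estimated correlation). Glycolysis gave 9 up and 1 down of 24 (10 and 2 adjusted over the list alone). The median was 0.45 (adjusted p = 0.306 with an estimated correlation). The 24 genes of the unfolded protein response gave 14 up and 1 down (15 and 1 adjusted over the list alone). The median was 0.48 (adjusted p = 0.352 with an estimated correlation). Among those called were calr at 45.6 ± 0.265 against 15.9 ± 2.12 CPM and the chaperone gene hspa5 at log2 1.27. The positional identity genes of appendages were not called as a list, with 9 of 27 up and 4 down (12 and 6 adjusted over the list alone). The median was 0.63 (camera adjusted p = 0.0894). The 9 higher members each lay under 20 CPM in both groups, and the 2 called members that reached it were lower proximally: crabp2a, a retinoic acid-binding protein gene (log2 -0.71), and the homeobox gene meis1b (log2 -0.67).

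Some listed genes were higher distally. Interferon response genes were lower after proximal amputation, 10 of 18 down (11 adjusted over the list alone). The median was -0.43 (camera adjusted p = 3.4e-06, and adjusted p = 0.306 with an estimated correlation). Those called included the immunoproteasome genes PSMB10 (8.85 ± 0.386 against 20.3 ± 1.11 CPM) and psmb8a (log2 -0.89) and HELZ2 (log2 -0.93). Of 31 circadian clock genes 11 were lower and 1 higher (13 and 1 adjusted over the list alone). The median was -0.44 (adjusted p = 0.376 with an estimated correlation). Of 22 G2 and M phase genes 9 were lower (10 adjusted over the list alone). The median was -0.38 (adjusted p = 0.352 with an estimated correlation). Among those called was top2a at 18.3 ± 0.680 against 26.0 ± 2.64 CPM. Of 27 genes of desmosomes and other junctions 9 were lower and 4 higher (10 and 5 adjusted over the list alone). The median was -0.50 (adjusted p = 0.352 with an estimated correlation). Upper epidermis-like cells made up 50.7% ± 1.71 of proximal and 80.5% ± 0.0747 of distal cells, and 4 of 11 superficial epidermis markers were lower and 2 higher (median -0.84).

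Within basal cells SAA was at 1.16 ± 0.673 against 65.3 ± 12.3 CPM (log2 -5.89, SE 0.34, edgeR adjusted p = 5.05e-06), ppdpfa at log2 -2.37, igsf10 at log2 -2.22 and DAPL1 at log2 -1.61, while FN1B (129 ± 89.3 against 45.8 ± 9.08 CPM), the chaperone gene clu (log2 1.51), the glypican gene GPC1 (log2 1.40), marcksl1a (log2 1.36), B4GALT7 (log2 1.28) and mmp13a (log2 1.15) were higher proximally. In all 66 basal genes were higher and 110 lower, and 321 and 443 with the run as a block. In upper cells 970 were higher and 832 lower, and 2460 and 2290 with the block; clu (log2 2.77), FN1B (log2 2.21) and the myosin gene myh9a (log2 1.71) led those higher, and SAA fell by log2 -6.06. The upper cells of the 2 groups came from different leading clusters, cluster 0 distally (23.6%) and cluster 2 proximally (18.7%). FN1B differed by 0.32 and 2.27 within the runs in basal cells, by 1.82 and 2.53 in upper cells and by 1.68 and 1.73 in mesenchyme-like cells.

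In mesenchyme-like cells 265 genes were higher and 317 lower, and 941 and 912 with the run as a block. WISP1, a matricellular growth factor gene, was at 54.2 ± 3.71 against 15 ± 1.52 CPM (log2 1.85, SE 0.18, edgeR adjusted p = 0.000188), FN1B at 339 ± 32.2 against 103 ± 7.28 CPM, ptx3a at log2 1.63, CYCSB, a cytochrome c gene, at log2 1.59, and the cargo receptor gene lman1 at log2 1.58. MSTNB, which encodes the muscle growth inhibitor myostatin, was lower (7.15 ± 0.0641 against 31.8 ± 6.80 CPM, log2 -2.14), as were SAA (log2 -2.69), the caveolar gene cavin2a (log2 -2.0), pamr1 (log2 -1.93) and the apolipoprotein E gene apoeb (log2 -1.74). SAA also leads an intermediate epidermis-like cluster, and krt5 was at 9155 CPM in the distal and 3840 CPM in the proximal mesenchyme-like sums, which therefore hold epidermal transcripts. Of 19 unfolded protein response genes 11 were higher (12 adjusted over the list alone). The median was 1.00 (adjusted p = 0.397 with an estimated correlation). Those called included hspa5 at log2 1.52 and HSP90B1 at log2 1.47. Of 32 proteasome genes 10 were higher (24 adjusted over the list alone). The median was 0.54 (adjusted p = 0.397 with an estimated correlation). In macrophage-like cells the distal group is 1 library, so no gene is named there.

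The proximal against distal counts depended on single libraries and on how cells were called and grouped. Over all cells 2462 and 2198 genes passed without distal replicates 1 and 2. In basal cells 10 passed without proximal replicate 2, 7 with a knee threshold and 1321 with the clusters kept out put back, in upper cells 887, 440, 731 and 328 without distal replicates 1 and 2 and proximal replicates 1 and 2, and in mesenchyme-like cells 287 without distal replicate 1, 919 without proximal replicate 1, 0 with the knee threshold and 2014 with the clusters put back. Those clusters held 20.8% ± 0.215 of proximal and 5.08% ± 0.492 of distal cells, the largest led by pyyb, SPP1, FN1 and FN1B (9.80% against 2.82%), and with them in the basal class mmp13a changed sign (log2 -0.03).

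In uncut dorsal fins of fish with a proximally amputated caudal fin, SAA was at 44.7 ± 7.14 CPM against 412 ± 305 CPM in uncut fish (n = 3 each, log2 -3.20, SE 0.43, edgeR adjusted p = 0.0133), where the 3 uncut libraries held 266, 208 and 763 CPM. S100A2 was at 167 ± 49.1 against 58.9 ± 7.12 CPM (log2 1.51, SE 0.25), the histone chaperone gene NASP at 71.6 ± 21.7 against 26.7 ± 10.3 CPM (log2 1.42), mcm6 at log2 1.35 and HELLS, a chromatin remodeller gene, at log2 1.31. H1F0, a linker histone gene, fell by log2 -1.74 and OLA.10900 by log2 -1.96. sqstm1 was lower (62.1 ± 5.05 against 79.8 ± 4.17 CPM, log2 -0.36, edgeR adjusted p = 0.034), and mmp13a (log2 1.00, adjusted p = 0.158) and mmp9 (log2 0.71, adjusted p = 0.271) did not pass.

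Over all cells 552 genes rose and 552 fell of 13710. Of 24 S phase genes 12 rose (19 adjusted over the list alone). The median was 0.98 (camera adjusted p = 1.6e-16, and adjusted p = 0.361 with an estimated correlation). Among those called were pcna at 425 ± 77.3 against 203 ± 59.0 CPM and MCM3 at log2 1.22. Of 23 unfolded protein response genes 10 rose (11 adjusted over the list alone). The median was 0.48 (adjusted p = 0.361 with an estimated correlation). Those called included HSP90B1 at log2 0.74. Of 33 ribosome biogenesis genes 8 rose (27 adjusted over the list alone). The median was 0.47 (adjusted p = 0.361 with an estimated correlation). Those called included the nucleolar chaperone gene NPM1A at log2 0.83. Of 34 proteasome genes 15 rose (23 adjusted over the list alone). The median was 0.43 (adjusted p = 0.361 with an estimated correlation). Interferon response genes were lower, 10 of 18 down (15 adjusted over the list alone). The median was -0.54 (adjusted p = 0.317 with an estimated correlation). Those called included PSMB10 at 25.9 ± 5.16 against 51.5 ± 6.85 CPM, psmb8a at log2 -0.86 and the class I light chain gene B2M at log2 -0.52. Of 27 genes of the matrix list 4 rose (16 adjusted over the list alone). The median was 0.97 (adjusted p = 0.361 with an estimated correlation). Mesenchyme-like cells were 8.56% ± 0.986 of these cells against 3.90% ± 1.17 in uncut fish, and 2 of 22 fibroblast markers rose (median 0.92).

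In basal cells of these fins 278 genes rose and 157 fell. calr rose from 3.48 ± 1.45 to 30.8 ± 9.94 CPM (log2 3.13, SE 0.31, edgeR adjusted p = 0.000147), the kinetochore genes spc25 (log2 2.17) and cenps (log2 1.98) rose, and so did the replication genes lig1 (log2 1.64), FEN1 (log2 1.63) and RPA1 (log2 1.54) and the tubulin-binding STMN1A (log2 1.57). SAA (log2 -1.83), the histocompatibility gene ORLA-UAA (log2 -1.62), H1F0 (log2 -1.45) and fsta, which encodes the activin antagonist follistatin (log2 -1.26), fell. Of 23 S phase genes 13 rose (20 adjusted over the list alone). The median was 1.21 (adjusted p = 0.254 with an estimated correlation). In upper cells 943 genes rose and 723 fell, and their largest cluster was cluster 0 (22.0%) in these fins and cluster 1 (24.8%) in uncut fish. In mesenchyme-like cells 10 rose and 18 fell, with pcna up (295 ± 22.6 against 175 ± 9.24 CPM, edgeR adjusted p = 0.0111), aspn (log2 1.53), anxa2b (log2 1.36) and NASP (log2 1.15) up and HER9, a Hairy-related repressor gene (log2 -1.36), and cd74a (log2 -1.09) down. Without proximal replicate 1 or 3 no gene passed over all cells, 542 passed without proximal replicate 2 and 197 without uncut replicate 1. In basal cells 85, 84 and 79 passed without proximal replicates 1 and 3 and uncut replicate 1, in upper cells 368, 638 and 723, and in mesenchyme-like cells 0, 11, 18 and 15 without proximal replicates 1 and 3 and uncut replicates 1 and 3, and 0 at the double clustering resolution.

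In uncut dorsal fins of fish with a distally amputated caudal fin, SAA was at 36.4 ± 4.32 CPM against 412 ± 305 CPM in uncut fish (log2 -3.50, SE 0.44, edgeR adjusted p = 0.0137). klf17 (ENSNFUG00015006071), a Krüppel-like factor gene listed here among the superficial epidermis markers, was at 190 ± 157 against 25.8 ± 1.86 CPM (log2 2.88, SE 0.64, adjusted p = 0.0214), with 197, 29.3 and 343 CPM in the 3 distal libraries. The transglutaminase gene tgm5l was at 224 ± 146 against 38.5 ± 0.492 CPM (log2 2.54), KLF2 rose by log2 1.54 and HELLS by log2 1.49, and OLA.10900 fell by log2 -1.92. sqstm1 was lower (64.2 ± 2.16 against 79.8 ± 4.17 CPM, log2 -0.32, edgeR adjusted p = 0.0369), and mmp13a (log2 1.32, adjusted p = 0.0658) and mmp9 (log2 0.79, adjusted p = 0.196) did not pass.

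**Figure D4:**
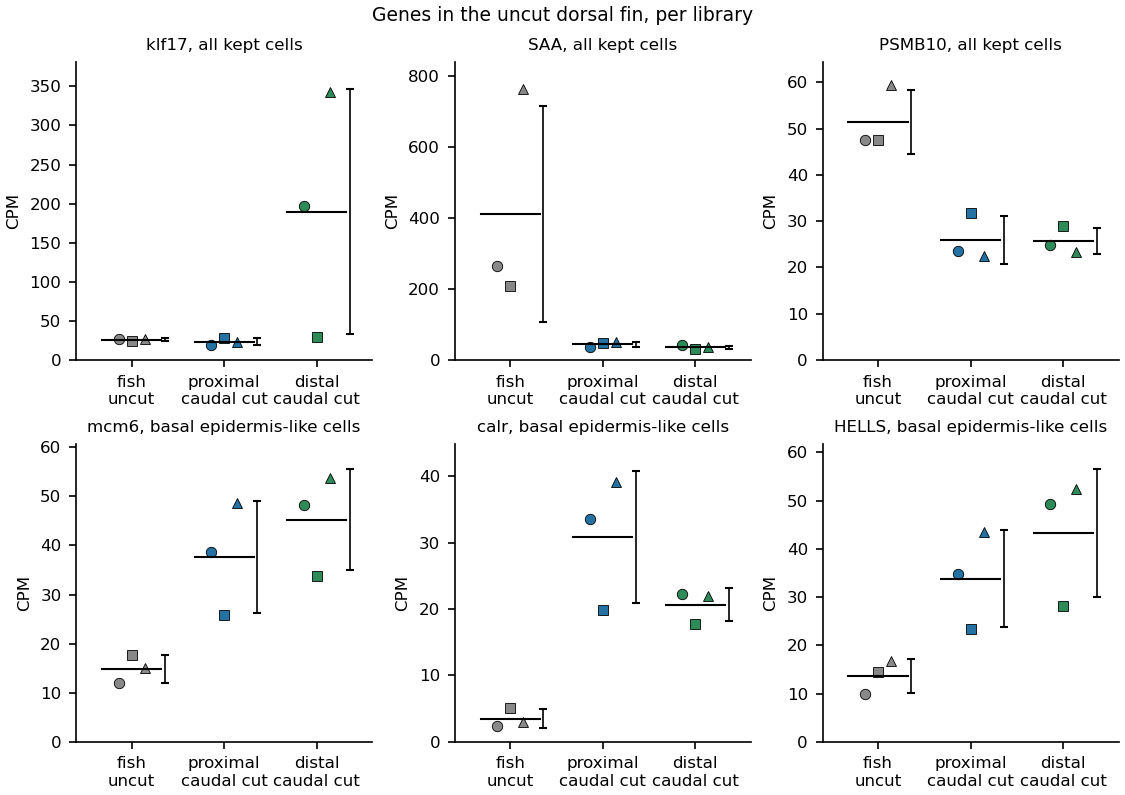
CPM of klf17, SAA and PSMB10 over all kept cells and of mcm6, calr and HELLS in basal epidermis-like cells of uncut dorsal fins of fish with an uncut, proximally amputated or distally amputated caudal fin, with 1 point per library, a line at the mean and a bar for the SD. SAA lies at 208 to 763 CPM in the 3 uncut libraries and at 32.3 to 50.1 CPM in the other 6, and klf17 at 197, 29.3 and 343 CPM in the distal libraries.

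Over all cells 994 genes rose and 766 fell after distal amputation. Of 33 ribosome biogenesis genes 27 rose (29 adjusted over the list alone). The median was 0.82 (camera adjusted p = 5.2e-27, and adjusted p = 0.454 with an estimated correlation). Among those called were NPM1A at log2 0.99 and BOP1 at log2 0.97. Of 24 S phase genes 12 rose (18 adjusted over the list alone). The median was 0.83 (adjusted p = 0.586 with an estimated correlation). Of 23 unfolded protein response genes 12 rose (13 adjusted over the list alone). The median was 0.54 (adjusted p = 0.454 with an estimated correlation). Those called included the asparagine synthetase gene ASNS at log2 1.45. Of 22 G2 and M phase genes 5 fell (6 adjusted over the list alone). The median was -0.81 (adjusted p = 0.822 with an estimated correlation). Among those called was CENPF at 6.99 ± 1.91 against 26.1 ± 18.5 CPM. Of 18 interferon response genes 6 fell (7 adjusted over the list alone). The median was -0.37 (adjusted p = 0.454 with an estimated correlation). Those called included PSMB10 at 25.7 ± 2.84 against 51.5 ± 6.85 CPM and IRF1B at log2 -1.29, and 5 of 16 macrophage markers were lower (median -0.47).

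In basal cells 503 genes rose and 473 fell, with klf17 (log2 2.65), calr (log2 2.58, SE 0.32, edgeR adjusted p = 0.00133), the cyclin-dependent kinase inhibitor gene CDKN1A (103 ± 61.3 against 21.8 ± 6.23 CPM) and KLF2 (log2 2.19) up, and fsta (log2 -1.81), H1F0 (log2 -1.73), AQP3 (120 ± 7.86 against 302 ± 3.61 CPM) and the anion channel gene LRRC8E (log2 -1.27) down. Of 23 S phase genes 19 rose (21 adjusted over the list alone). The median was 1.32 (adjusted p = 0.417 with an estimated correlation). Of 55 ribosomal protein genes 52 fell (53 adjusted over the list alone, with 1 up). The median was -0.37 (adjusted p = 0.431 with an estimated correlation). In upper cells 1188 genes rose and 1118 fell, and their largest cluster was cluster 4 (30.2%) after distal amputation and cluster 1 (24.8%) in uncut fish. In mesenchyme-like cells 23 rose and 11 fell; S phase passed with both correlations, with 5 of 18 genes up (16 adjusted over the list alone). The median was 1.01 (camera adjusted p = 1.5e-22, and 0.0263 with an estimated correlation). The replication clamp gene pcna was at 386 ± 12.1 against 175 ± 9.24 CPM, mmp13a at 34.3 ± 18.2 against 4.17 ± 3.07 CPM (log2 2.89), CHAF1A at log2 1.5, and ID1, an inhibitor of basic helix-loop-helix factors, at log2 -0.89. Over all cells no gene passed without distal replicate 1 or 3, and 533 passed without uncut replicate 1. In basal cells 310, 1630 and 154 passed without distal replicates 1, 2 and 3 and 239 and 591 without uncut replicates 1 and 3, in upper cells 789, 543 and 1301 without distal replicates 1 and 3 and uncut replicate 1, and in mesenchyme-like cells 1, 135 and 18 without distal replicates 1, 2 and 3, 8, 125 and 1 without uncut replicates 1, 2 and 3, and 0 at the double clustering resolution.

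The comparisons of both amputations with uncut fish share their 3 uncut libraries. Over all cells 388 genes rose and 370 fell in both, where independent calls would give 40 and 30.8. Shared controls make log2 changes correlate by themselves: the correlation across genes, which are not independent replicates, was 0.661 over all cells against 0.501 in simulated unchanged data with the same controls, 0.753 against 0.529 in basal cells, 0.814 against 0.489 in upper cells and 0.581 against 0.565 in mesenchyme-like cells. In 20 simulations at most 0 genes were called in both comparisons over all, basal or upper cells, and at most 1 in mesenchyme-like cells. The covariances exceeded the simulated ones by 0.101, 0.137, 0.148 and 0.0325. Each gene was simulated on its own, so no simulated control library deviates over many genes at once. Between uncut replicates 1 and 2 the chi-square per degree of freedom was 12.17, but replicate 3 gave 108.8 and 126.9 against them. How many shared genes come from the shared controls therefore cannot be told from these simulations. The 3 controls are too few to be split into a pair of groups with at least 2 libraries each.

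Proximal and distal caudal amputation were also compared directly in the uncut dorsal fin. No gene passed with edgeR over all cells or in basal, upper or mesenchyme-like cells, where 1511, 851, 797 and 589 genes had an unadjusted p under 0.05 and DESeq2 called 73, 4, 7 and 1. The smallest p belonged over all cells to OLA.20275 (log2 2.65, adjusted p = 0.122), the galectin gene LGALS1 (log2 1.44, adjusted p = 0.122) and the retinol dehydrogenase gene RDH10A (log2 2.46, adjusted p = 0.211), and in basal cells to rasd1 (log2 -4.35, edgeR adjusted p = 0.0674), the ferritin gene FTH1A and fkbp5, a glucocorticoid-induced co-chaperone gene (11.8 against 84.0 CPM, adjusted p = 0.114). In mesenchyme-like cells they were anxa2b (log2 1.43, adjusted p = 0.114), OLA.20275 and KRT18, and in upper cells Nfu_g_1_024366, ccl25a and PRSS35 (adjusted p = 0.73). The differences were -0.05 for sqstm1 (adjusted p = 0.868), -0.32 for mmp13a (adjusted p = 0.818) and -0.08 for mmp9 (adjusted p = 0.955). The matrix list differed with the preset correlation, with 0 of 27 genes called and 17 higher after proximal amputation adjusted over the list alone (median log2 1.09, camera adjusted p = 1e-20, and adjusted p = 0.475 with an estimated correlation), beside a median of 0.94 for 22 fibroblast markers. Without distal replicate 2 the direct comparison called 53 genes over all cells, 255 in basal, 35 in upper and 67 in mesenchyme-like cells.

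The shares of cell classes differed in 5 tests. At caudal 12 hpa basal cells made up 4.64% ± 0.525 of kept cells (n = 3) against 7.45% ± 1.33 in the uncut fin (n = 4, log2 -0.69, edgeR adjusted p = 0.0172, exact permutation p = 0.0286), and mesenchyme-like cells 11.8% ± 5.35 against 5.53% ± 1.15 (log2 1.08, edgeR adjusted p = 0.046, exact permutation p = 0.0857). Clusters kept out of the classes held 8.07% of caudal 12 hpa cells and 1.97% of uncut cells. The largest of them scored 0.709 as intermediate and 0.66 as basal epidermis, so leaving it out could lower the basal share at 12 hpa. After proximal against distal amputation mesenchyme-like cells were more frequent (log2 1.24), as were neutrophil-like cells (1.09% against 0.278%) and endothelial cells (0.504% against 0.125%), each with an edgeR adjusted p of 0.0461 and an exact permutation p of 0.333, the smallest that 2 against 2 libraries can give. No share passed in the dorsal fin at 12 hpa, in the interaction or in the dorsal fins of fish with an amputated caudal fin, where mesenchyme-like cells, at 8.56% ± 0.986 after proximal and 3.55% ± 1.5 after distal amputation, had the smallest p (0.0105 unadjusted, 0.127 adjusted with edgeR, 0.1 exact). With TMM factors over classes 0 of the 5 passed and at the double clustering resolution 3.

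**Figure D5:**
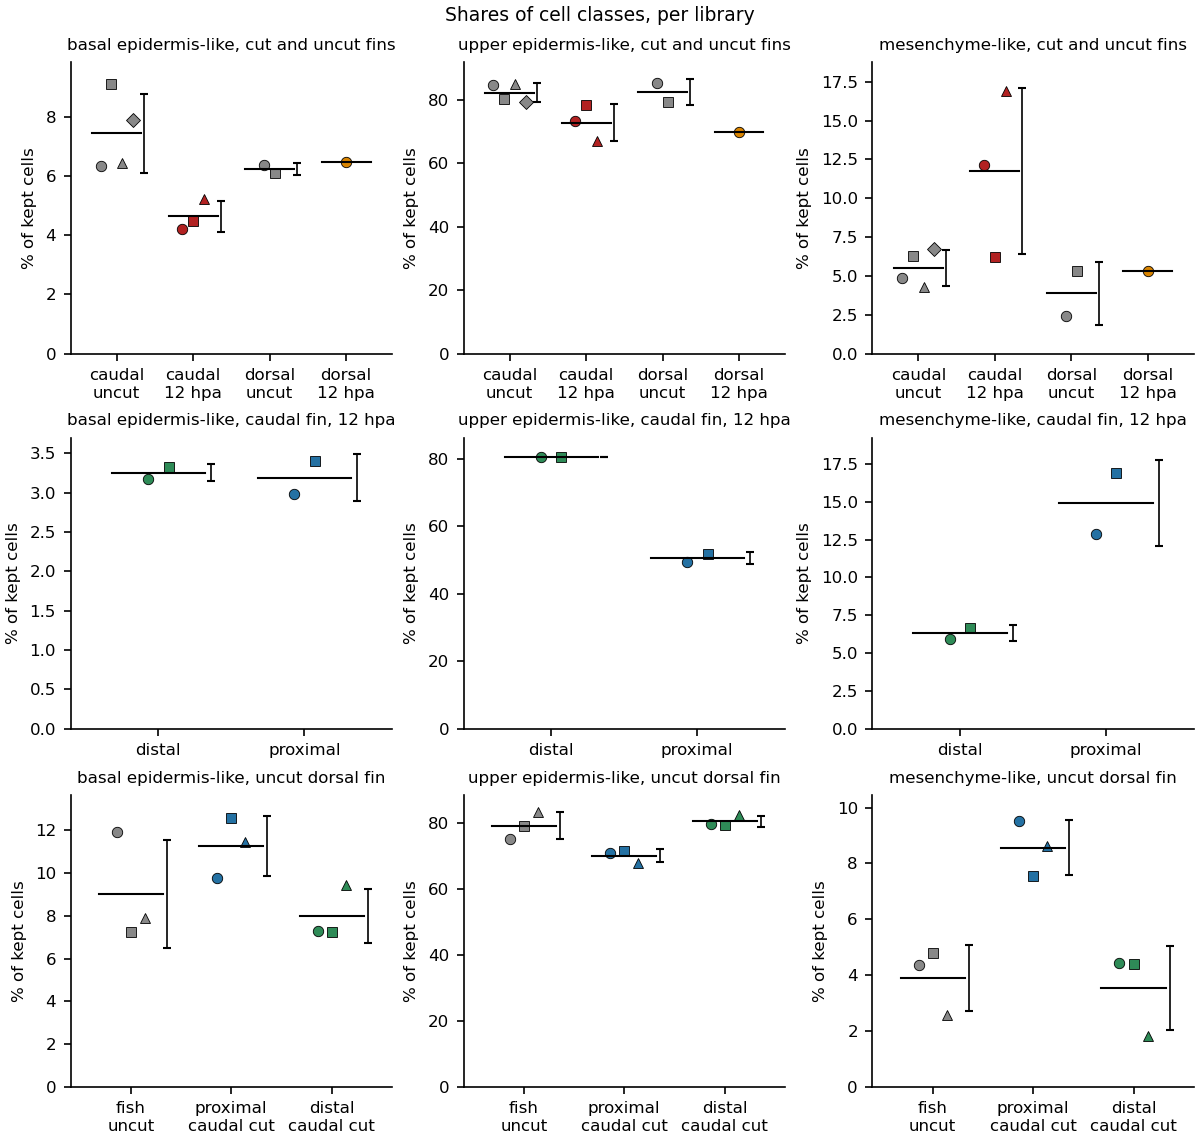
Share of kept cells (percent) in the basal epidermis-like, upper epidermis-like and mesenchyme-like classes per library in the 3 sets, with 1 point per library, a line at the group mean and a bar for the SD. Mesenchyme-like cells make up 14.9% of cells after proximal and 6.31% after distal caudal amputation, and 8.56% and 3.90% in dorsal fins of fish with a proximally amputated and an uncut caudal fin.

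Genes that changed at caudal 12 hpa were looked up in the other libraries, which were not used to choose them. In basal cells of the uncut dorsal fin, 67 of the 108 measured genes that rose at caudal 12 hpa rose after proximal caudal amputation and 0 fell (87 up adjusted over the list alone). The median was 0.77 (camera adjusted p = 3.4e-63, and 0.0166 with an estimated correlation). In the same cells 24 of the 60 that fell were lower (39 adjusted over the list alone). The median was -0.49 (0.0198 with an estimated correlation). After distal amputation 58 of 108 rose (75 adjusted over the list alone). The median was 0.65 (0.0363 with an estimated correlation). Of the other 60 genes 29 fell (41 adjusted over the list alone). The median was -0.55 (0.0363 with an estimated correlation). Independent calls would give 4.43 shared genes up and 1.41 down after proximal and 8.01 and 4.23 after distal amputation, and calr, lig1 and cenps rose in basal cells in all 3 of these comparisons. In upper cells 65 of 200 genes that rose at 12 hpa rose and 7 fell after proximal amputation (median 0.32, adjusted p = 0.311 with an estimated correlation), and 45 rose and 22 fell after distal amputation (median 0.03, camera adjusted p = 0.0568). Over all cells 60 of 197 rose and 1 fell after proximal amputation, and 46 rose and 10 fell after distal amputation. The medians were 0.37 and 0.16 (adjusted p = 0.189 and 0.51 with an estimated correlation). Of the genes called both at caudal 12 hpa and after distal amputation, 254 rose and 137 fell in both and 55 went opposite ways over all cells (independent calls would give 101 and 45.8 shared), and 311, 111 and 87 did so in upper cells (130 and 58), and the log2 changes correlated at 0.113 and 0.123 across genes, which are not independent replicates. After proximal against distal amputation of the caudal fin, 114 of 200 genes that fell at 12 hpa were lower and 3 higher (140 and 6 adjusted over the list alone). The median was -0.50 (adjusted p = 0.0518 with an estimated correlation). The 200 genes that rose at 12 hpa went both ways, with 78 higher and 40 lower (85 and 42 adjusted over the list alone). The median was 0.17 (adjusted p = 0.166 with an estimated correlation).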

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

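The tests of explanations for the 3 patterns and of other splits were chosen after the results were seen, except those of library depth and of free RNA for FN1B in upper epidermis-like cells.

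The first pattern is the level of klf17, fkbp5 and KLF2 in the uncut dorsal fins of fish with a distally amputated caudal fin. These are genes of Krüppel-like factors and of a glucocorticoid-induced co-chaperone, and klf17 stood at 197, 29.3 and 343 CPM in the 3 distal libraries. Free RNA from upper epidermis-like cells is argued against for fkbp5, whose basal-to-upper ratio was at least 1.34 in distal libraries 1 and 3, where the superficial epidermis markers ran from 0.166 to 0.764. For klf17 and KLF2 it stays open, since their ratios, from 0.553 to 0.757, lay within that range. A rise of at least 2 times in every distal library is argued against for klf17 and fkbp5, whose lowest distal library reached at most 1.07 times the highest uncut one. For KLF2 it stays open, since that ratio was 1.40. A response of single samples to handling or stress cannot be told apart from other differences between the samples, because no label records handling, and the highest distal klf17 value was 11.7 times the lowest.

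The second pattern is the rise of S phase genes, and of the basal genes that rose at caudal 12 hpa, in the uncut dorsal fins of fish with an amputated caudal fin. Uncut replicate 3 alone is argued against, since without it the lowest median of these gene sets in both comparisons was 0.72, against 0.65 with it, although the distal count fell from 976 to 591 in basal and from 34 to 1 in mesenchyme-like cells. A shift in the shares of cell classes is argued against, since the lowest median of the S phase genes within the 3 classes was 0.77. A shift between clusters within a class stays open, since the leading upper cluster differed between the groups. The mesenchyme-like sums also hold epidermal transcripts. Library depth stays open, since thinning the basal sums to equal UMIs keeps expected ratios. The basal genes up at 12 hpa had a median of 0.80 thinned and 0.77 before. Cell numbers and UMIs per cell were not matched. A response of the dorsal fin to the injury of the caudal fin may explain it, as a hypothesis found on the same data, and part of the likeness of the 2 comparisons could come from their shared controls, since only 3 uncut libraries served both.

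The third pattern is the higher level of matrix genes after proximal than after distal caudal amputation. For the whole list, more mesenchyme-like cells could explain it, as within those cells its median was -0.29 (camera adjusted p = 0.454). For FN1B a larger share of mesenchyme-like cells is argued against as the whole cause in upper and mesenchyme-like cells, where its smallest log2 difference within a run was 1.68. In basal cells it stays open, since the 2 runs gave 0.32 and 2.27. Free RNA from mesenchyme-like cells is argued against for FN1B in upper cells, where its ratio to mesenchyme-like cells was 45.9 times that of COL1A2 in the lower proximal library. Position along the fin, and the share or free RNA of the clusters kept out, stay open, untested.

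Of all splits of the 7 caudal libraries into 4 and 3, the real one called the most genes for 3 of 4 counts. First place among 35 is a share of 0.0286, not adjusted over the counts, so chance is unlikely there but not excluded. The real split was the 1 of 35 with as many genes over all cells (2239, highest other 3), in basal cells (173, highest other 49) and in upper cells (2012, highest other 233). In mesenchyme-like cells 8 of 35 splits called at least as many as the real 1, up to 57. That count does not stand out from chance. The split with 57 points to a structure of these sums that was not identified.

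For each pair of groups of 3 dorsal libraries there are 10 splits, too few for a share under 0.05. After proximal amputation the real split gave 1104, 435, 1666 and 28 genes over all, basal, upper and mesenchyme-like cells, and the highest other split 133, 5, 184 and 5. After distal amputation it gave 1760, 976, 2306 and 34 genes, and the highest other split 0, 1, 0 and 3. In each of these 8 tests 1 of the 10 splits reached the real value. Between proximal and distal amputation the real value was 0 with edgeR in each of the 4, which all 10 splits reach, and the highest other split gave 2, 25, 0 and 1 genes.

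Among 47 groups tested for a library far from the others, 3 had one, where chance gives about 1 in 20. The ratio of the gap to the range was held against Dixon's critical value for 4 libraries. All 3 were in the uncut caudal fin, the only group with 4 libraries, so their place there says nothing particular about that fin. The ratio was 0.893 for the median UMIs of a library (17750), 1.0 for mmp13b and 0.854 for CENPF in upper epidermis-like cells (3.45 CPM). The mmp13b value lay near the floor, at 0.07 CPM.

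The caudal and dorsal responses at 12 hpa differed in 7 gene lists with the preset correlation, and in 0 with an estimated one. The median log2 difference, caudal less dorsal, was -0.42 for the unfolded protein response, -0.20 for heat shock and chaperones, -0.36 for S phase, 0.49 for retinoic acid metabolism and response, -0.53 for ribosome biogenesis, 0.12 for ribosomal proteins and -0.19 for the proteasome.

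In the uncut dorsal fin 16 lists differed between proximal and distal caudal amputation with the preset correlation, and 0 with an estimated one (adjusted p from 0.475 to 0.801). The median log2 difference, proximal less distal, was 1.09 for provisional and fibrillar matrix, 0.43 for the basement membrane, 0.38 for integrins and matrix receptors, 0.24 for metalloproteinases and protease regulators and 0.12 for the actin cytoskeleton. It was 0.40 for positional identity genes, 0.35 for fin regeneration signals, 0.34 for G2 and M phase, 0.14 for retinoic acid metabolism and response and 0.13 for the proteasome. It was -0.29 for the glucocorticoid response, -0.27 for ribosome biogenesis, -0.25 for inflammatory cytokines, -0.21 for the interferon response, and -0.07 for immediate early genes and -0.07 for ribosomal proteins.

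In macrophage-like cells of the same fins 6 genes were lower after proximal amputation, but the comparison sets 1 library against 1 with a spread taken from the uncut libraries, so the amputation and the single libraries cannot be told apart. The log2 differences were -4.68 for ENSNFUG00015003039, -6.13 for ENSNFUG00015020436, -3.18 for ENSNFUG00015024760, -3.08 for MFAP4, -3.86 for acod1 and -5.45 for OLA.16268. Of these, OLA.16268, ENSNFUG00015003039 and ENSNFUG00015020436 are among the leading genes of neutrophil-like clusters and MFAP4 of mucous cell-like clusters, so other cells in the macrophage-like class stay open as well.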

How the results depend on the processing

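The clusters put back, the top barcodes and the 1 UMI floor were chosen after the data were seen, and the other alternatives before the data were examined. Among the values of named genes under the alternatives, 10176 kept their direction and their side of the threshold, 1792 kept their direction and were no longer called, 57 were called in addition and 22 changed sign. DESeq2's size factors left each count over all kept cells, and in each class, within 1.5 times. The minimum of 1000 UMIs removes no cell of the first set, so it says nothing there. In the other sets it left each count within 1.5 times. The cause was not tested for the results that moved. Below, proximal and distal systemic stand for the uncut dorsal fins of fish with a proximally or distally amputated caudal fin against uncut fish, direct systemic for the first against the second, mesenchyme and macrophages for the classes like them, and the number for genes called. In macrophages 1 distal library stands against 2 proximal ones at caudal 12 hpa, and 1 library per amputated group in the dorsal fins, so their numbers, from 77 in proximal against distal and 30, 25 and 6 in proximal, distal and direct systemic, say nothing on stability.

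With DESeq2's Wald test, the caudal and dorsal difference gave 9 in all cells, 1 in upper cells and 1 in mesenchyme and dorsal 12 hpa gave 2 in basal cells. Caudal 12 hpa gave 18 in mesenchyme and proximal against distal gave 99 in basal cells, 267 in mesenchyme and 4 in macrophages. Proximal systemic gave 1694 in all cells, 53 in mesenchyme and 14 in macrophages and direct systemic gave 73 in all cells, 4 in basal cells, 7 in upper cells, 1 in mesenchyme and 1 in macrophages. Distal systemic gave 126 in mesenchyme and 8 in macrophages. With no filter on low counts, the caudal and dorsal difference gave 3 in all cells, 4 in basal cells, 30 in upper cells and 43 in mesenchyme and caudal 12 hpa gave 313 in basal cells and 175 in mesenchyme. Dorsal 12 hpa gave 51 in basal cells and 88 in mesenchyme and proximal against distal gave 382 in basal cells and 927 in mesenchyme. Direct systemic gave 3 in all cells, 129 in basal cells, 17 in upper cells and 151 in mesenchyme and proximal systemic gave 676 in basal cells, 162 in mesenchyme and 55 in macrophages. Distal systemic gave 211 in mesenchyme and 41 in macrophages.

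With the replicate number as a block, caudal 12 hpa gave 293 in basal cells and 3 in mesenchyme and dorsal 12 hpa gave 7 in basal cells. The caudal and dorsal difference gave 2 in mesenchyme and proximal against distal gave 7577 in all cells, 764 in basal cells, 4750 in upper cells and 1853 in mesenchyme. Direct systemic gave 11 in basal cells and 1 in mesenchyme. At the double clustering resolution, caudal 12 hpa gave 453 in basal cells and 5 in mesenchyme and dorsal 12 hpa gave 0 in mesenchyme. Proximal systemic gave 0 in mesenchyme and distal systemic gave 0 in mesenchyme. Of the shares of cell classes 3 passed. With each tissue's own libraries, dorsal 12 hpa gave 42 in basal cells and 47 in mesenchyme and caudal 12 hpa gave 4 in mesenchyme.

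With the clusters kept out put back, dorsal 12 hpa gave 2136 in upper cells and caudal 12 hpa gave 0 in mesenchyme. Proximal against distal gave 1321 in basal cells and 2014 in mesenchyme and direct systemic gave 5 in basal cells. Without doublet removal, caudal 12 hpa gave 5 in mesenchyme and proximal against distal gave 279 in basal cells. Proximal systemic gave 15 in mesenchyme and 10 in macrophages and distal systemic gave 8 in macrophages. Direct systemic gave 2 in macrophages. With a knee threshold, proximal against distal gave 2338 in all cells, 7 in basal cells, 1011 in upper cells and 0 in mesenchyme. With the top barcodes up to the deposited cell count, proximal against distal gave 2238 in all cells, 56 in basal cells and 21 in macrophages. With 1 UMI floor, proximal against distal gave 237 in mesenchyme.

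With the 30K files alone, direct systemic gave 1 in all cells and 8 in basal cells and proximal systemic gave 256 in basal cells and 7 in mesenchyme. Distal systemic gave 11 in mesenchyme. With the 50K files alone, proximal systemic gave 711 in all cells, 225 in basal cells and 16 in mesenchyme and distal systemic gave 541 in basal cells and 1 in mesenchyme. With TMM factors over classes, 0 shares of cell classes passed. With the estimated correlation, 7 tests of fixed gene lists and 5 of the 12 hpa sets in other runs passed.

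With each replicate left out in turn, counts ran as follows. For caudal 12 hpa they ran from 1182 to 1975 in all cells, 53 to 222 in basal cells, 1148 to 1749 in upper cells and 1 to 49 in mesenchyme. For the caudal and dorsal difference they ran from 0 to 4 in all cells, 0 to 1 in basal cells, 0 to 1 in upper cells and 0 to 2 in mesenchyme. For dorsal 12 hpa they ran from 392 to 1521 in all cells, 0 to 0 in basal cells, 228 to 1342 in upper cells and 0 to 0 in mesenchyme. For proximal against distal they ran from 2198 to 4139 in all cells, 10 to 237 in basal cells, 328 to 887 in upper cells and 287 to 919 in mesenchyme. For distal systemic they ran from 0 to 2383 in all cells, 154 to 1630 in basal cells, 543 to 2834 in upper cells, 1 to 135 in mesenchyme and 15 to 77 in macrophages. For direct systemic they ran from 0 to 53 in all cells, 0 to 255 in basal cells, 0 to 35 in upper cells and 0 to 67 in mesenchyme. For proximal systemic they ran from 0 to 1090 in all cells, 79 to 451 in basal cells, 368 to 1818 in upper cells, 0 to 33 in mesenchyme and 10 to 91 in macrophages.

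For sqstm1 at caudal 12 hpa the log2 fold change was 0.003 with no filter, 0.002 without doublet removal, 0.049 and 0.025 without 12 hpa replicates 2 and 3 and 0.070 without uncut replicate 1, and its lowest value was -0.085, without 12 hpa replicate 1. For mmp13b it was -2.197 at caudal 12 hpa without 12 hpa replicate 2, and 1.088 in the caudal and dorsal difference without caudal uncut replicate 4. Its other extremes were 4.152 at caudal 12 hpa without uncut replicate 4 and -5.252 in the difference without caudal 12 hpa replicate 2. For mmp9 in that difference it was 0.203 without doublet removal, 0.235 and 0.174 without caudal 12 hpa replicates 2 and 3, 0.373 without caudal uncut replicate 3 and 0.204 without dorsal uncut replicate 2, with a lowest value of -1.310 without caudal 12 hpa replicate 1. In proximal against distal, mmp13a was at -0.029 and FTL at 0.163 in basal cells with the clusters put back, and tpm4a in upper cells at -0.140 with the knee threshold and -0.229 with the top barcodes. In direct systemic, mmp13a was at 0.109 without distal replicate 3 and 0.019 without proximal replicate 2, and mmp9 at 0.185 with the 50K files, 0.157 without distal replicate 3, and 0.187 and 0.025 without proximal replicates 2 and 3. Their lowest values, without proximal replicate 1, were -0.736 for mmp13a and -0.576 for mmp9.

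In simulations 40.3% of 2-fold changes were recovered in caudal mesenchyme-like cells, against 69.7% over all cells.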

Other observations

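No test was chosen here after a result was seen, since only values follow. Across the sums over all kept cells of the 7 comparisons, the lists of ribosome biogenesis, ribosomal proteins and the proteasome were called in 7 with the preset correlation, those of the unfolded protein response, heat shock, S phase and the interferon response in 6, and those of oxidative stress with autophagy and of the lysosome in 0. With an estimated correlation 4 of the 25 lists were called at caudal 12 hpa, 2 at dorsal 12 hpa and 0 in the other 5 comparisons. Over all cells sqstm1 passed in dorsal fins after each caudal amputation against uncut fish (log2 -0.36 and -0.32).

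The mitotic gene CENPF was at 26.1 ± 18.5 CPM in the dorsal fins of uncut fish and at 6.99 ± 1.91 CPM after distal amputation. In mesenchyme-like sums krt5 stood at 26650, 22320 and 35260 CPM in dorsal fins after distal, after proximal and without caudal amputation. These sums therefore hold epidermal transcripts. At caudal 12 hpa 515 genes rose that were also higher after proximal than distal amputation, where independent calls would give 207, and 145 genes went opposite ways.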
